A study of Mus musculus with 8 samples.

How the data were processed

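RNA from mouse colon was hybridised to 8 one-colour Agilent arrays, 1 array per sample, 4 labelled colon tumor and 4 labelled normal colon. Per the labels, the mice were C57BL/6, RNA was total RNA labelled with Cy3, and each sample is a separate tissue sample. The labels of the tumors give the genotype as heterozygous for both Tcf4 and Apc, and those of the normals as wild type for Tcf4 and heterozygous for Apc. Tissue and Tcf4 genotype were therefore confounded in every comparison.

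Per the file headers, the scanner files hold spot intensity values that were background-subtracted and detrended by the extraction software and not normalised between arrays. Per the file headers, they were extracted with Agilent Feature Extraction 9.5.1.1 from arrays of design 014868 with probe coordinates on mm8, while the submitters' processing notes name Feature Extraction 10.1.1.1. Each file held 41174 non-control probes. The share of probes that the scanner software flagged as well above background ran from 55.6% to 82.8% over the 8 files. The other deposited kind of value is the authors' table with 1 column per sample, whose scale no label states. It was found to be log2, because in its 4 traceable columns the values rose by 0.891 to 1.06 per unit of log2 scanner intensity (linear fit over probes, Pearson correlations of at least 0.982), and quantile-normalised by the authors, because each column had the median 8.51 and the 75th percentile 11.40.

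Columns of the deposited value table were set against every scanner file. Of the 8 columns, 4 matched a file with a Spearman correlation of 1.0000 and with empty cells at exactly the 9, 11, 46 and 55 probes flagged as non-uniform in that file. Only 1 of these 4 matched the file of its own sample, tumor 1. Column normal 1 matched the file under normal 2, column normal 2 the file under normal 3, and column tumor 2 the file under normal 4. The remaining 4 columns matched no file, with a highest correlation of 0.9890, and 4 files matched no column, with a highest correlation of 0.9724. The 4 files without a column lie at positions 2 and 4 of the 2 slides.

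The plan made before the data were examined was to fit the scanner values as filed, as log2 signal minus each array's 75th percentile. Because scanner files and value columns disagree on which array belongs to which sample, the value table was used instead, with each sample taken from its column's label. No sample was moved to another group. This choice was made after the files and some marker levels had been seen. The planned fit called 0 of 21676 genes and had 433 at an unadjusted p under 0.05, so every result below depends on this choice. Which of the deposited sets carries the right labels for all samples is not settled by the files. The 4 files without a column, under normal 1 and tumors 2, 3 and 4, had high levels of small intestine genes and low levels of distal colon genes. Relative to each array's 75th percentile, their small intestine list means were 2.13 to 4.08, against -2.83 to -0.96 in the matching files. Their distal colon list means were -5.57 to -3.35, against 0.095 to 0.79. These levels argue against distal colon as the tissue of those 4 files. The planned fit therefore mixed them with the other files, mostly on the tumor side.

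A probe was kept when its value was at or above 5.59 on at least 4 of the 8 arrays. That limit, also set after the files were seen, is the median over the 4 traced columns of the 95th percentile of probes not well above background. The percentiles were 4.50 in tumor 1, 7.70 in normal 1, 5.82 in normal 2 and 5.35 in tumor 2. In normal 1 the limit placed 79.1% of probes on the same side as the scanner flag, so values above 5.59 there can be background. In all 31871 probes were kept. Gene names came from the files' accessions and names through a table of RefSeq genes of assembly GRCm38.p6, used for names only. Of the 41174 probes, 24375 were named by accession, 6301 by symbol and 2426 by synonym, and 8072 kept the file's name. The brightest kept probe stood for each gene, which left 21638 genes. Of 7241 genes with over 1 kept probe, 8 had probes called in opposite directions and 1298 had some probes called and others not.

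Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Values are log2, differences are tumor minus normal, and errors are SD over n = 4 for levels and SE for differences. The median difference of all genes tested was 0.15 (0.048 without the filter), but this shift was uneven. It was 1.11 over 621 genes whose symbols open with Olfr, 1.06 over 82 with Vmn and -0.11 over 328 with Zfp. Differences are to be read against a shift that reached that size in some gene groups, and its cause was not tested. The precision is limited by 4 arrays per group. A group whose arrays were all below the limit would have been given a bound, but no named gene was in that position. The 35 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Some lists share members, such as Timp1, Thy1, Mmp7, Wif1, Lef1 and Tcf7, so their results are not separate evidence. Genes to be named followed a rule fixed at the same time: Tcf7l2 and Apc, the 10 largest rises and 10 largest falls among called genes with groups that did not overlap and with a gene symbol, not an accession, clone or predicted-gene name, in the files, up to 4 called members of each list by lowest adjusted p (or the 2 lowest p where none was called), and the sex-linked genes; 2 genes under this rule are not reported here.

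The labels number the samples 1 to 4 in each group. Deviations of same-numbered samples from their group means correlated at 0.24, 0.36, 0.53 and 0.36, all above 0.1, so the numbers were taken to pair the samples. Of the different-numbered pairs, tumor 1 with normal 3 (0.28), tumor 2 with normal 4 (0.35) and tumor 4 with normal 2 (0.38) were also above 0.1, and tumors 1 and 4 correlated best with a normal of another number, so the pairing rests on that rule alone. The main fit was planned without a block and has no pair term, so its counts and p-values ignore the pairs. With the number as a block 1869 genes changed, against 3147 in the main fit, and 38 of 129 named genes lost their call. Fits with the number as a block are given where they change a call. The traced columns of pair 1 lie on slide 1 and those of pair 2 on slide 2. The slides of the other 4 columns are unknown, so slide could not be used as a block over all 8 columns. Rescaling of the value table was not tried because its columns already share 1 distribution. Other alternatives were another dim-probe filter, the mean over probes, array weights, a trended variance prior, each array left out in turn, and the scanner values as filed under 4 scalings and a slide block.

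The fit was tested on simulated data with the genes' own means and spreads. In 20 simulations over 21638 genes with 200 changed genes, a mean of 57.5 of 100 genes with a log2 change of 2 and 23.8 of 100 with a log2 change of 1 were recovered, and 5.63% of calls were false. Noise was drawn independently for each gene, with no pair effect and no outlying sample. The 5.63% is therefore no estimate of the false share among calls in the real data.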

Results

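Gene expression was measured in 4 colon tumors and 4 normal colon samples of C57BL/6 mice that carry 1 mutant copy of Apc, the gene of the scaffold protein that marks beta-catenin for destruction. The tumors, described as adenomas, came from mice that also carry 1 mutant copy of Tcf4, the older name of Tcf7l2, which encodes the main beta-catenin partner at Wnt target genes in gut epithelium. The normals came from mice wild type for Tcf4. The protocol names the distal 2.5 cm of the colon, from mice of both Tcf4 genotypes, as the source of RNA. Whether the normals came from colon that bore tumors is not given in the sources used here. The comparison asks how tumor tissue differs from normal colon. It cannot separate the tumor state from the Tcf4 genotype. Values are from the authors' log2 table, because scanner files and table columns disagreed on sample identity, as described with the processing.

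**Figure D1:**
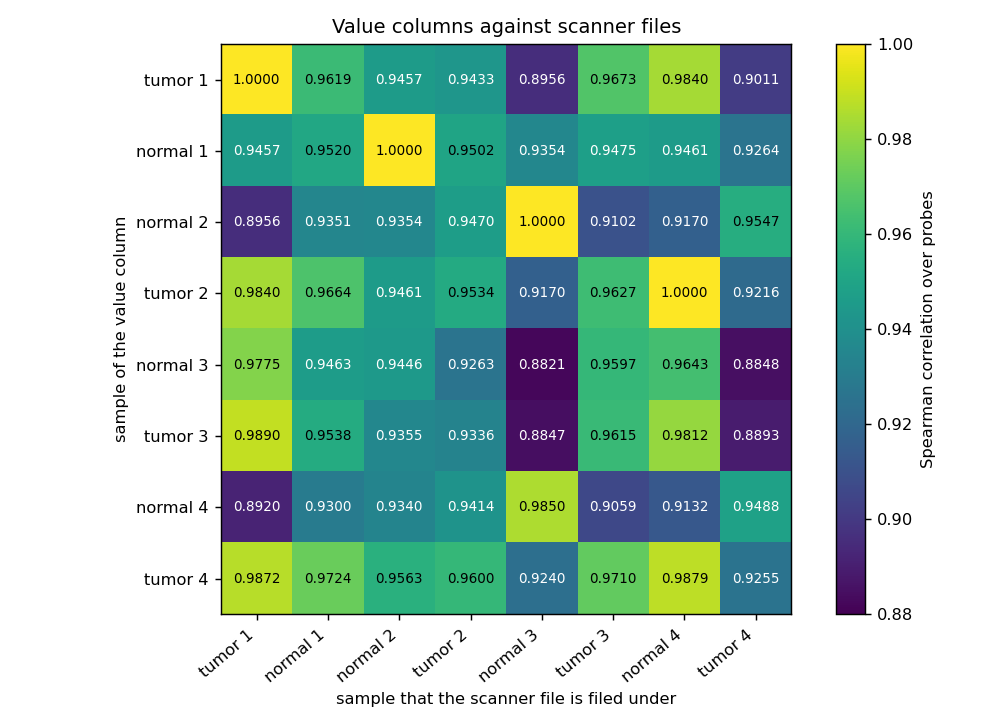
Spearman correlation over probes of each column of the authors' value table (rows) with each scanner file (columns), both named by the sample they are filed under. A value of 1, at 4 decimals, marks the same array; it lies on the diagonal for tumor 1 alone, off the diagonal for 3 other columns, and is absent from 4 columns.

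Tcf7l2 itself was lower in the tumors, at 12.81 ± 0.38 (SD, n = 4) against 14.56 ± 0.31 (SD, n = 4) in the normals. It fell by 1.75 ± 0.24 (SE) on the log2 scale, 3.37-fold, with a limma adjusted p of 0.0145 (0.0361 with the pairs as a block). The groups did not overlap, and the difference was -1.42, -2.15, -1.86 and -1.59 in pairs 1 to 4, of which the first lies within slide 1 and the second within slide 2. The probe lies on chromosome 19 at 55986346 to 55986405 (mm8). A second probe at 55985220 to 55985279 gave -1.78, and another at 55961735 to 55961794 gave -0.80 with an adjusted p of 0.0622. A probe at 55978171 to 55978230 was too dim for the fit, with a mean of 3.94 in tumors, all 4 below the detection limit of 5.59, and of 7.07 in normals, of which normal 3 (4.64) was below it. Exon annotation on mm8 was not used here, so the position of the probes relative to the mutated part of the gene is unknown. The call was lost without tumor 3 (-1.60, adjusted p = 0.0549) and without normal 4 (-1.68, adjusted p = 0.0517). Apc, read by a probe on chromosome 18 at 34446596 to 34446655 (mm8), was 11.56 ± 0.24 in tumors and 11.92 ± 0.19 in normals (difference -0.36 ± 0.17, adjusted p = 0.177). The 6 Apc probes differed in sign, from -1.47 to 1.27.

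Across all genes, 3147 of 21638 changed in the limma fit, 1515 higher and 1632 lower in tumors, and 1741 changed at least 2-fold (876 higher, 865 lower). Over all genes, the sample labelled normal 3 correlated at 0.947 to 0.966 with the tumors and at 0.872 to 0.941 with the other normals (Pearson). The groups did not overlap for 5159 genes, 23.8% against 2.86% by chance. That chance value takes all samples as exchangeable and ignores the pairs. Among genes that the files name by a symbol and whose groups did not overlap, the largest rises were in the matrix metalloproteinase Mmp10 (6.40 ± 1.28, adjusted p = 0.0231), the neutrophil chemokine Cxcl2 (5.93 ± 1.41, adjusted p = 0.034), the neutrophil collagenase Mmp8 (5.70 ± 1.07, adjusted p = 0.0208) and the Wnt ligand Wnt10a (5.46 ± 1.34, adjusted p = 0.0367). Adcy8, Reg2, S100a8, Retnlg, Onecut2 and S100a9 rose by 5.43, 5.43, 5.41, 5.33, 5.30 and 5.25. Levels of Mmp8 were above the detection limit in 1 of 4 normals, and those of Cxcl2, Adcy8 and Onecut2 in 3 of 4, so their folds depend on dim values. In column normal 1 probes not well above background reached 7.70 at their 95th percentile. Further rises may therefore depend on dim values too. The largest falls were in the lipid droplet protein Hsd17b13 (-4.53 ± 0.80, adjusted p = 0.0192), the cytochrome P450 Cyp2c55 (-3.65 ± 0.62, adjusted p = 0.018) and the transporter Slc37a2 (-3.58 ± 0.48, adjusted p = 0.0145). Slc6a19, Tmigd1, Tgm3, Kcnf1, Otc, Abcb1a and Afm changed by -3.14, -3.09, -3.02, -3.01, -2.94, -2.91 and -2.87, with Slc6a19 above the limit in 1 of 4 tumors. With the pairs as a block, the counts were 1869 changed, 780 higher and 1089 lower, and Wnt10a, Adcy8 and Onecut2 missed the threshold at adjusted p of 0.057, 0.0591 and 0.0611. The count moved by over 1.5 times whichever sample was left out, from 21 without tumor 3 and 160 without normal 4 to 11138 without normal 3, and scanner values as filed gave 0 genes in limma with 433 at an unadjusted p under 0.05.

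**Figure D2:**
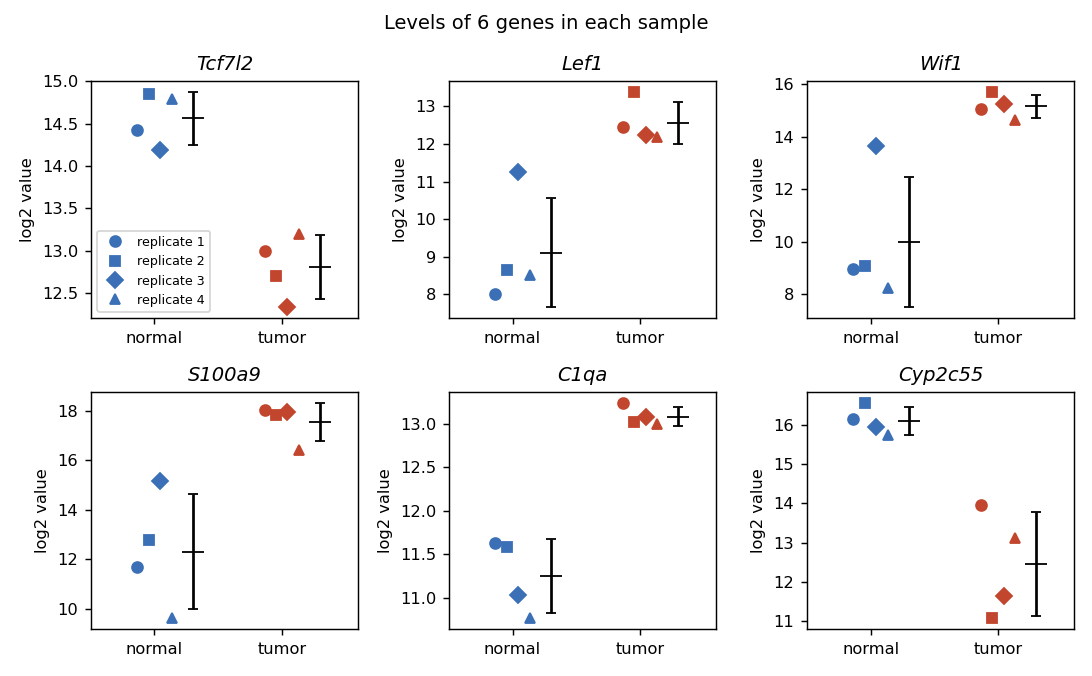
Log2 value of Tcf7l2, Lef1, Wif1, S100a9, C1qa and Cyp2c55 in each sample, 1 panel per gene, normals in blue and tumors in red; symbols give the replicate number, and black bars the mean ± SD of 4 samples. In Wif1 the sample labelled normal 3 (13.65) lies nearer to the tumors (mean 15.16) than to the other normals, while in C1qa (11.03) and Cyp2c55 (15.95) it lies with the normals.

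Of 35 gene lists, 20 shifted by camera with a preset correlation, 12 up and 8 down, and 0 with an estimated correlation, where the lowest adjusted p was 0.353. Of 35 lists, 19 moved on balance 1 way by fry and 28 changed in either direction. In what follows, camera p-values are adjusted over the 35 lists.

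Wnt target genes rose in tumors: 20 of 26 rose, 0 fell and 6 did not pass (23 rose when adjusted over the list alone, and 6 rose with the pairs as a block). The mean change was 2.38 and the camera adjusted p was 2.37e-09 (adjusted p = 0.353 with an estimated correlation). Among them were Cd44, a cell surface receptor (1.90 ± 0.35, adjusted p = 0.02), Rnf43, a ubiquitin ligase that removes Wnt receptors (1.58 ± 0.31, adjusted p = 0.0227), and the guidance receptor Ephb3 (0.80 ± 0.15, adjusted p = 0.0199). Znrf3, another such ligase, rose by 0.96 ± 0.19 (adjusted p = 0.0223, 0.0561 with the block). The mean level of the list was 12.41 in the sample labelled normal 3, against 10.26 to 10.27 in the other 3 normals and 12.89 to 13.61 in the tumors. Of Wnt ligands, receptors and secreted inhibitors, 7 of 35 rose and 3 fell (9 and 3 over the list alone, 3 and 3 with the block), without a list shift (camera adjusted p = 0.203). The secreted inhibitor Wif1 rose by 5.18 ± 1.12 (adjusted p = 0.027), Wnt6 by 4.08 ± 0.80 (adjusted p = 0.0221) and Dkk3 by 1.81 ± 0.26 (adjusted p = 0.0149), and the receptor Fzd5 fell by 1.53 ± 0.22 (adjusted p = 0.0149). Among TCF/LEF factors and nuclear cofactors, 2 of 22 rose and 4 fell (2 and 4 over the list alone, 1 and 2 with the block; camera adjusted p = 0.241, with a list mean of 0.10 and a median of -0.12). Of the genes most like Tcf7l2, Lef1 rose by 3.45 ± 0.70 (adjusted p = 0.0235, 0.0512 with pairs as a block) and Tcf7 from 9.77 ± 0.84 to 11.76 ± 0.34 (SD, n = 4; adjusted p = 0.0242). Tcf7l1, named after its values were seen, fell by 1.23 ± 0.32 (adjusted p = 0.0437, 0.052 with the block). The corepressor Tle4 fell by 1.07 ± 0.21 (adjusted p = 0.0219, 0.0531 with the block).

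Intestinal stem cell markers and ribosome biogenesis genes also rose, and cell cycle genes rose with groups that overlapped. Of the stem cell markers, 6 of 17 rose and 1 fell (11 and 2 over the list alone, 3 and 0 with the block, mean 0.63, camera adjusted p = 0.00965). The list shares Lgr5, Ascl2, Tnfrsf19, Axin2, Sox9 and Rnf43 with the Wnt target list, and Rnf43 and Sox9 are 2 of its 4 named genes. Cdca7 rose by 0.99 ± 0.17 (adjusted p = 0.0178), Smoc2 by 0.94 ± 0.19 (adjusted p = 0.0235) and Sox9 by 0.78 ± 0.16 (adjusted p = 0.0251, 0.0645 with the block). Of 24 ribosome biogenesis genes, 9 rose and 0 fell (21 and 0 over the list alone, 4 and 0 with the block; mean 0.64, camera adjusted p = 1.97e-06), among them the nucleolar methyltransferase fibrillarin, Fbl (0.72 ± 0.14, adjusted p = 0.0215), and Nip7 (0.95 ± 0.20, adjusted p = 0.0269). Nhp2 rose by 1.45 ± 0.31 (adjusted p = 0.025, 0.0501 with the block) and Nop56 from 14.66 ± 0.30 to 15.66 ± 0.28 (SD, n = 4; adjusted p = 0.0248, 0.0526 with the block). Of 30 cell cycle genes, 8 rose and 0 fell (10 and 0 over the list alone, 2 and 0 with the block; mean 0.39, camera adjusted p = 0.00219). The 4 named were Mcm3, Mcm7, Mcm5 and Mcm4, subunits of the replicative helicase, with rises of 0.78, 0.76, 0.66 and 0.65. The last 3 missed the threshold with the block (adjusted p of 0.0525, 0.0597 and 0.0569). With an estimated correlation these 3 lists had adjusted p = 0.353, 0.363 and 0.576. The ligand and receptor genes of the BMP and TGF-beta list split, with 8 of 24 up and 2 down (9 and 2 over the list alone; camera adjusted p = 0.0926). Bmp7 rose by 2.55 ± 0.31 (adjusted p = 0.0123), Inhba by 3.40 ± 0.52 (adjusted p = 0.0163) and Inhbb by 2.62 ± 0.42 (adjusted p = 0.0167), and Bmp3 fell from 11.01 ± 0.36 to 9.51 ± 0.40 (SD, n = 4; adjusted p = 0.0187). Of 19 Notch genes, 1 rose and 3 fell (the same counts over the list alone, 0 and 1 with the block; camera adjusted p = 0.961), with Nrarp, a Notch target, down by 1.20 ± 0.23 (adjusted p = 0.0215). Hey1 was at 1.68 ± 0.35, Hes1 at -0.64 ± 0.15 and Dll1 at -0.86 ± 0.22 (adjusted p = 0.0241, 0.0345 and 0.0418; 0.0559, 0.067 and 0.0769 with the block). Of 12 hedgehog genes 1 rose, Smo by 0.53 ± 0.13 (adjusted p = 0.0355, 0.0638 with the block; camera adjusted p = 0.481; 1 over the list alone, 0 with the block).

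Genes of the mature absorptive epithelium fell. Of 29 absorptive colonocyte markers, 0 rose and 18 fell (22 over the list alone; mean -1.61, camera adjusted p = 2.91e-11). Besides Cyp2c55 and Slc37a2, the amino acid transporter Slc6a14 fell by 1.88 ± 0.29 (adjusted p = 0.0162) and Hsd11b2, which inactivates glucocorticoids, by 1.96 ± 0.33 (adjusted p = 0.0179). Of 24 fatty acid oxidation and ketogenesis genes, 12 fell and 1 rose (18 and 1 over the list alone, 9 and 0 with the block; mean -0.79, camera adjusted p = 1.89e-08). They included the regulators Ppara (-2.32 ± 0.32, adjusted p = 0.0149) and Ppargc1a (-1.48 ± 0.21, adjusted p = 0.0149) and the carnitine carrier Slc25a20 (-1.12 ± 0.15, adjusted p = 0.0147), and Acadm was at -1.21 ± 0.21 (adjusted p = 0.0183). Of 20 pan-epithelial genes, 5 fell and 0 rose (11 fell and 3 rose over the list alone, 2 fell with the block; mean -0.42, camera adjusted p = 0.000268). The transcription factors Cdx1 (-1.53 ± 0.24, adjusted p = 0.0165) and Hnf4a (-1.24 ± 0.24, adjusted p = 0.0215) were among them. Cdh17 fell by 1.02 ± 0.21 and Gpa33 changed by -1.74 ± 0.40 (adjusted p = 0.0248 and 0.0311; 0.0528 and 0.052 with the block). Of 18 enteroendocrine markers, 5 fell and 0 rose (10 fell over the list alone, 3 with the block; mean -0.68, camera adjusted p = 0.00069). The secretory granule chaperone Scg5 was among them (-1.25 ± 0.25, adjusted p = 0.0232). Chga, Gcg and Pax4 changed by -1.21 ± 0.27, -1.62 ± 0.39 and -0.94 ± 0.23 (adjusted p = 0.0287, 0.034 and 0.0345; 0.0698, 0.0592 and 0.0709 with the block). Of 9 genes of distal colon position, 6 fell and 1 rose (7 and 1 over the list alone, 3 and 1 with the block; mean -0.73, camera adjusted p = 0.00472). Among them were Wfdc2 at -1.08 ± 0.16 (adjusted p = 0.0149) and the homeobox gene Hoxa11 at 1.11 ± 0.18 (adjusted p = 0.0174). Hoxd11 was at -1.87 ± 0.39 (adjusted p = 0.0244, 0.0507 with the block). With an estimated correlation each of these 5 lists had adjusted p = 0.353. The sample labelled normal 3 had a colonocyte list mean of 14.93, within 14.77 to 14.96 in the other normals.

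By camera, goblet cell markers were lower and Paneth and antimicrobial genes higher in tumors, but the groups overlapped in the goblet list. Of 20 goblet cell markers, 2 fell and 0 rose (1 fell over the list alone, 0 with the block; mean -0.37, camera adjusted p = 0.0148, and adjusted p = 0.574 with an estimated correlation). Bcas1 fell by 1.55 ± 0.31 (adjusted p = 0.0226, 0.0501 with the block) and the secretory lineage factor Atoh1 differed by -1.86 ± 0.49 (adjusted p = 0.045, 0.052 with the block). The goblet list call was lost without normal 1 or without tumor 2. Of 17 Paneth and antimicrobial genes, 2 rose and 0 fell (4 rose over the list alone; mean 1.63, camera adjusted p = 0.012, and adjusted p = 0.38 with an estimated correlation). The 2 were Mmp7 (4.56 ± 1.20, adjusted p = 0.0441, 0.0555 with the block) and Habp2 (3.02 ± 0.55, adjusted p = 0.0199), the latter above the detection limit in 1 of 4 normals. Mmp7 is also on the Wnt target and metalloproteinase lists. Of 14 tuft cell markers, 3 rose and 0 fell (3 over the list alone, 1 with the block; camera adjusted p = 0.0681). They were the actin-binding protein gene Avil (2.85 ± 0.72, adjusted p = 0.0402, 0.0582 with the block), the phospholipase gene Plcg2 (0.73 ± 0.15, adjusted p = 0.0249) and the cyclooxygenase gene Ptgs1 (0.58 ± 0.12, adjusted p = 0.026, 0.0633 with the block).

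Inflammatory and matrix-degrading genes had the largest list means. Of 22 neutrophil and acute inflammation genes, 19 rose and 0 fell (19 over the list alone; mean 3.84, camera adjusted p = 5.38e-09). Il11, a cytokine of the interleukin 6 family, rose by 4.77 ± 0.65 (27.2-fold, adjusted p = 0.0145), Lcn2, which binds bacterial siderophores, by 5.16 ± 0.73 (adjusted p = 0.0149), and Ptgs2, the inducible cyclooxygenase, by 3.49 ± 0.40 (adjusted p = 0.0123). Clec4d rose by 4.07 ± 0.58 (adjusted p = 0.0149). Of 18 matrix metalloproteinases and plasminogen activators, 13 rose and 0 fell (15 over the list alone; mean 2.69, camera adjusted p = 2.07e-06). They included Mmp9 (3.43 ± 0.33, adjusted p = 0.00864), Mmp14 (1.20 ± 0.21, adjusted p = 0.0183) and the inhibitor Timp1 (2.92 ± 0.47, adjusted p = 0.0167). Mmp12 rose by 3.24 ± 0.46 (adjusted p = 0.0149) and was above the detection limit in 2 of 4 normals. Of 20 monocyte and macrophage genes, 9 rose and 1 fell (11 and 1 over the list alone, 8 and 0 with the block; mean 1.03, camera adjusted p = 7.69e-05). Cd68 rose by 1.61 ± 0.16 (adjusted p = 0.00909), the complement component C1qa by 1.83 ± 0.22 (adjusted p = 0.0123) and the Fc receptor Fcgr3 by 2.29 ± 0.25 (adjusted p = 0.0123). C1qb rose by 1.35 ± 0.18 (adjusted p = 0.0145). Of 15 immediate early and heat shock genes, 5 rose and 0 fell (7 rose and 1 fell over the list alone, 3 rose with the block; mean 0.84, camera adjusted p = 0.00484), including Hspb1 (1.77 ± 0.21, adjusted p = 0.0123). Ier3 rose by 3.28 ± 0.61 (adjusted p = 0.0204), Hsph1 by 1.49 ± 0.33 (adjusted p = 0.0295) and Jun by 0.90 ± 0.22 (adjusted p = 0.0345, 0.0501 with the block). With an estimated correlation these 4 lists had adjusted p = 0.353. The mean level of the macrophage list was 10.84 in the sample labelled normal 3, below the other normals (11.45 to 11.92). In the other lists of this paragraph, normal 3 lay between the other normals and the tumors. Its neutrophil list mean was 10.255, with other normals at most 8.84 and tumors at least 11.58. Its metalloproteinase list mean was 11.29, with other normals at most 10.06 and tumors at least 12.38. For immediate early genes it was 13.196, with other normals at most 13.03 and tumors at least 13.55.

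Some of the other stromal and immune lists shifted. Of 20 T and NK cell genes, 5 rose and 0 fell (6 over the list alone; mean 0.75, camera adjusted p = 0.0059, and adjusted p = 0.356 with an estimated correlation). The T cell kinases Zap70 and Lck rose by 2.30 ± 0.32 (adjusted p = 0.0149) and 0.98 ± 0.18 (adjusted p = 0.0199). Il2rb rose by 1.14 ± 0.25 (adjusted p = 0.0281) and Cd3d by 1.32 ± 0.32 (adjusted p = 0.0363, 0.0674 with the block). Of 17 endothelial genes, 5 rose and 0 fell (8 over the list alone, 3 with the block; mean 0.85, camera adjusted p = 0.00241, and adjusted p = 0.363 with an estimated correlation). Egfl7 rose by 1.27 ± 0.15 (adjusted p = 0.0123) and Cdh5 by 1.14 ± 0.21 (adjusted p = 0.0204). Plvap rose by 0.71 ± 0.17 (adjusted p = 0.0329, 0.0713 with the block) and Sox17 from 10.17 ± 2.18 to 14.23 ± 0.51 (SD, n = 4; adjusted p = 0.0367, 0.059 with the block). Of 22 fibroblast and matrix genes, 4 rose and 0 fell (5 over the list alone; mean 0.86, camera adjusted p = 0.00965, and adjusted p = 0.592 with an estimated correlation). Vimentin, Vim, rose by 1.63 ± 0.26 (adjusted p = 0.0167). Of the risen genes, Timp1 is also on the metalloproteinase list and Thy1 on the T and NK cell list. Thy1 rose by 1.17 ± 0.29 (adjusted p = 0.0372) and Sparc by 1.57 ± 0.41 (adjusted p = 0.0448, 0.0696 with the block). The fibroblast call was lost without normal 3. Interferon response genes did not shift as a list (2 of 20 rose, 2 over the list alone; camera adjusted p = 0.392), although Cxcl9 rose by 2.47 ± 0.29 (adjusted p = 0.0123) and Usp18 by 2.90 ± 0.43 (adjusted p = 0.0151). Of 20 B and plasma cell genes 1 rose (0 over the list alone, 0 with the block; camera adjusted p = 0.426), Sdc1 by 0.86 ± 0.20 (adjusted p = 0.0319, 0.0554 with the block). Of 20 glycolysis genes, 2 rose and 2 fell (2 and 4 over the list alone, 1 and 1 with the block; camera adjusted p = 0.102). The glucose transporter Slc2a3 was at 1.23 ± 0.26 (adjusted p = 0.0245) and the hexokinase Hk1 at -0.92 ± 0.21 (adjusted p = 0.0302). Gpi1 was at -0.55 ± 0.14 and Slc16a3 at 2.09 ± 0.53 (adjusted p = 0.0378 and 0.0401; 0.0635 and 0.0775 with the block).

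Muscle genes differed between samples rather than between groups. Of 20 smooth muscle genes and 12 skeletal muscle genes, 0 rose and 0 fell (0 over each list alone), although camera placed both lists lower in tumors (means -0.47 and -1.98, adjusted p = 0.0403 and 0.0448, and adjusted p = 0.61 and 0.592 with an estimated correlation). The skeletal muscle list mean was 14.47 in normal 4, 12.82 in normal 2 and 12.30 in tumor 3, against 7.88 in normal 1 and 8.06 in tumor 2. The smooth muscle call was lost without any of normal 2, tumor 2, tumor 3 or normal 4, and the skeletal muscle call without any of tumor 1, normal 2, tumor 2, normal 3, normal 4 or tumor 4. The fast muscle myosin Myh1 was 7.62 ± 3.69 in tumors and 12.67 ± 4.49 in normals (adjusted p = 0.198), above the detection limit in 2 of 4 tumors. Myh2, Myh11 and Casq2 differed by -2.09 ± 1.18, -1.22 ± 0.62 and -0.61 ± 0.30 (adjusted p = 0.221, 0.197 and 0.194). Of 18 enteric neuron and glia genes, 2 fell (0 over the list alone; camera adjusted p = 0.0926, 0.0263 with the block), the neurofilament genes Nefl (-1.28 ± 0.34, adjusted p = 0.0446) and Nefm (-1.73 ± 0.48, adjusted p = 0.0495, 0.052 with the block). Of 11 adipocyte genes 0 were called (0 over the list alone; camera adjusted p = 0.0926, 0.0485 with the block), of 14 squamous epithelium genes 0 (0 over the list alone; camera adjusted p = 0.487) and of 5 red blood cell genes 0 (0 over the list alone; camera adjusted p = 0.425). Values in these lists were -0.45 ± 0.15 for Pnpla2 and -0.97 ± 0.42 for Cidec, -2.60 ± 0.74 for Trp63 and 3.53 ± 1.14 for Krt15, and 1.82 ± 0.81 for Alas2 and 1.44 ± 0.64 for Hba-a1 (adjusted p = 0.0794, 0.154, 0.0541, 0.0776, 0.165 and 0.165), with Trp63 above the limit in 1 of 4 tumors. The squamous list had a mean of 0.00 and a median of -0.16. Of 16 small intestine genes, 1 rose and 3 fell (1 and 4 over the list alone, 0 and 1 with the block; camera adjusted p = 0.0546), with the glucose transporter Slc5a1 at -1.44 ± 0.20 (adjusted p = 0.0149). Rbp2 was at -1.40 ± 0.36 and Cubn at 2.45 ± 0.65 (adjusted p = 0.0435 and 0.0457; 0.0525 and 0.0698 with the block). Of 5 sex-linked genes 0 were called (0 over the list alone; camera adjusted p = 0.199), and the Y-linked Eif2s3y was 13.53 ± 0.16 in tumors and 13.80 ± 0.09 in normals (adjusted p = 0.193). Xist differed by 0.71 ± 0.49, and the Y-linked Uty, Ddx3y and Kdm5d by -0.39 ± 0.23, -0.24 ± 0.15 and -0.44 ± 0.27 (adjusted p = 0.29, 0.233, 0.256 and 0.243).

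**Figure D3:**
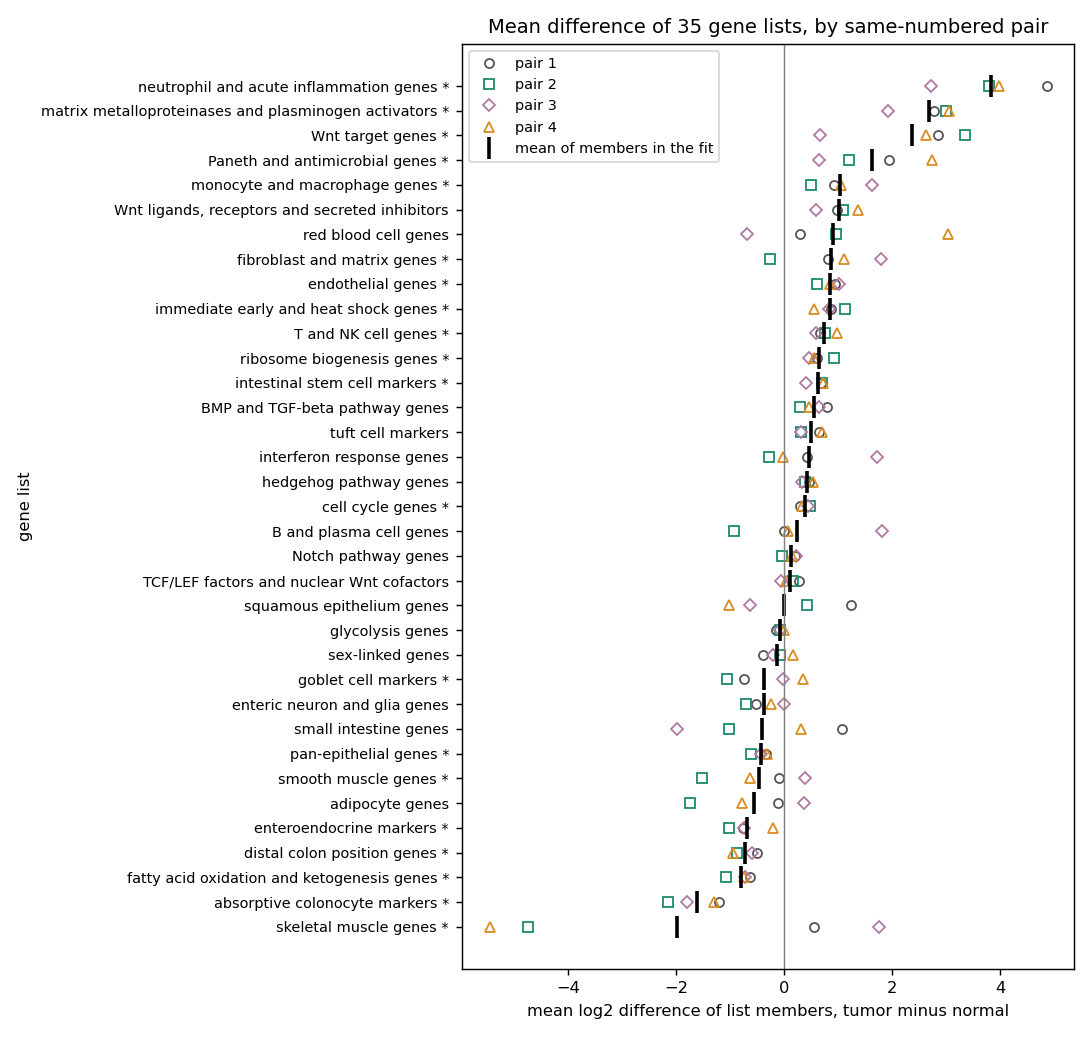
Mean log2 difference (tumor minus normal) over the members of each of 35 gene lists, open symbols for each same-numbered pair and a black bar for the mean change in the fit of 8 samples; an asterisk marks a camera adjusted p under 0.05 at the preset correlation. In the neutrophil list the 4 pairs lie between 2.71 and 4.86, while in the skeletal muscle list pairs 2 and 4 lie at -4.75 and -5.45 and the other pairs above 0.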

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

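All tests of explanations below were chosen after the values they concern had been seen. Of 332 groups of 4 values (named genes and list means, per group), 24 had a sample whose gap to its nearest neighbour exceeded Dixon's critical value for 4 values at 95% confidence as a share of the group's range. Chance alone gives about 1 in 20. The sample labelled normal 3 was the outlying sample in 13 of the 24.

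In the normals, the sample labelled normal 3 stood apart in the Wnt target list, at 12.41 with a gap of 0.996 of the range, and in the Wnt genes Wnt10a (0.928), Wnt6 (0.917), Wif1 (0.843), Tcf7 (0.938) and Rnf43 (0.848), in all of which it was higher. It was also higher in Nop56 (0.972), Avil (0.831) and Lcn2 (0.836), and lower in Hsd11b2 (0.896), Atoh1 (0.896), the goblet list (0.847) and the B and plasma cell list (0.861). An exchange of labels with a tumor of this series would need a tumor at normal Wnt levels, and 0 of 4 tumors had a Wnt list mean at or below the highest of the other normals. Over all genes normal 3 was nearer to the tumors than to the other normals (Pearson correlations of 0.947 to 0.966 against 0.872 to 0.941), and on the first principal component (67.3%) it lay at -74.1, within the tumors (-92.0 to -39.1) and apart from the other normals (36.9 to 150). A tumor like these 4 labelled as normal would lie within them in all lists as well, but normal 3 lay outside their spread in 2 of 35 lists by a prediction interval with BH adjustment, those of macrophage genes (10.84 against 12.40 to 12.50) and distal colon position (12.24 against 11.55 to 11.65). Tissue like any of the 4 tumors mixed into colon like normals 1, 2 and 4 would give all tumor-high genes about the same share. The median share was 38.4% over 14 Wnt targets and 11.6% over 20 myeloid and inflammation genes, a difference of 26.8 percentage points (largest permutation p over the 4 possible sources 0.0023, with genes not independent). Shares were taken on the linear scale from quantile-normalised values. Normal 3 lay below normals 1, 2 and 4 in the macrophage list (10.84 against 11.45 to 11.92), so its normal part need not be like them. The shares therefore argue only against a mixture with colon like those normals, and mixing into other normal colon was not tested. A tumor or lesion of other make-up, as the whole sample or part of it, may still be the source, and no biological explanation was tested, because the design sets no normal apart.

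The 4 scanner files that match no value column were used in no comparison of table values. The mean of 16 small intestine genes was 5.09 higher in them than in the 4 matching files on the log2 scale (3.04 against -2.05, relative to each array's 75th percentile; exact permutation p = 0.0286, the smallest 4 against 4 can give, adjusted p = 0.0571 over 4 lists). Sucrase-isomaltase, Sis, was 7.61 higher, and Hoxb13 was well above background in 4 matching files and in 1 of these 4. Arrays of lower signal would lower the list without scaling too, but its lowest mean in the 4 files lay 3.57 above its highest in the matching files. The distal colon list differed by -5.47 (exact permutation p = 0.0286; 6 of 9 genes were well above background in at most 1 of the 4 files, so its size is not a measured fold), with no overlap in either list, so arrays of another gut segment filed under these samples are a candidate explanation that the data allow. The levels of both lists argue against distal colon as the tissue of these 4 files, while the labels name no tissue other than colon.

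At the probe used, Tcf7l2 fell by more than the loss of 1 of 2 gene copies gives at equal expression, a log2 change of -1. The 95% interval of the change at that probe was -2.31 to -1.20, so -1.20 is the nearest bound to -1. With the mean over the kept probes of the gene, the change was smaller, at -1.45 ± 0.21 (SE), and no interval was computed for it. At the probe with the smallest change the difference was -0.80 ± 0.24 (SE), which leaves room for a change of -1, so the excess was not shown at every probe. A smaller share of epithelial cells in the tumors was argued against as the whole cause, since the median change of 20 pan-epithelial genes was -0.44 with a median absolute deviation of 0.46, although 6 of the 20 fell by over 1. Loss of 1 copy and a smaller epithelial share were each tested alone, so both acting together were not tested and stay open. Probe positions relative to the mutated part of the gene, and lower Tcf7l2 expression in tumor cells, also stay open and may contribute beside the -1.20 bound. Tissue and genotype were confounded.

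Other outlying samples were normal 1 in Ephb3 (0.89), Slc25a20 (0.857) and the TCF/LEF list (0.838). In the tumors they were tumor 1 in Tle4 (0.838), tumor 2 in Jun (0.861) and the B and plasma cell list (0.922), tumor 3 in Apc (0.868) and Myh1 (0.831), and tumor 4 in S100a9 (0.857), Fcgr3 (0.889) and Krt15 (0.857).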

How the results depend on the processing

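Settings for the 4 traced samples, the scanner detection flag on traced arrays and the block without pair 3 were chosen after seeing the data, as were the use of the value table and its detection limit of 5.59. The other kinds of setting were set before. Gene counts moved most with the set of values used, the samples included and array weights, and the count of lists with the correlation used in camera.

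Scanner values as filed gave 0 genes changed, 0 higher, 0 lower and 0 changed at least 2-fold in limma under each of 5 settings, with 433, 428, 466, 443 and 324 genes at an unadjusted p under 0.05 (75th percentile, normexp, quantile, median centring, slide block). Lists shifted were 14, 13, 13, 12 and 13, and the Tcf7l2 difference was -0.75, -0.74, -0.73, -0.93 and -0.75, none past the threshold. Of the genes called from the table, 2062 of 3118 kept their sign with the 75th percentile. Of 128 named genes, 39 changed sign at the 75th percentile and 80 kept their sign but lost their call. As 0 genes were called in that setting, called genes among the 39 lost their call too. The reversed differences were Reg2 -1.38, Slc6a19 4.26, Tmigd1 3.30, Otc 2.46, Abcb1a 0.31, Ephb3 -0.014, Znrf3 -0.13, Fzd5 0.53, Dkk3 -0.0079, Smoc2 -0.010, Sox9 -0.40, Nip7 -0.045, Gcg 0.52, Pax4 0.14, Hnf4a 0.33, Cdh17 0.39, Vim -0.24, Thy1 -0.057, Sparc -0.28 and Mmp12 -0.31. They were also Mmp14 -0.19, Sdc1 -0.079, Nrarp 0.091, Dll1 0.54, Bmp3 0.34, Smo -0.44, Gpi1 0.040, Ppara 1.03, Hspb1 -0.74, Hsph1 -0.067, Jun -0.36, Pnpla2 0.15, Cidec 1.39, Krt15 -0.36, Slc5a1 1.53, Rbp2 2.13, Hoxa11 -2.92, Alas2 -0.47 and Hba-a1 -0.31. Of the lists with a call in either fit, the direction turned for stem cell markers (mean 0.18), ribosome biogenesis (-0.058), enteroendocrine markers (0.082), pan-epithelial genes (0.13), fibroblast and matrix genes (-0.25), matrix metalloproteinases (0.37), fatty acid oxidation (0.12), immediate early genes (-0.13) and small intestine genes (3.42), where camera's direction is that relative to all genes. Lists of Wnt target (0.73), cell cycle (0.10), goblet cell (0.15) and neutrophil and acute inflammation genes (0.36) lost their call, and those of tuft cell (0.65), B and plasma cell (0.53), interferon response (0.44) and glycolysis genes (-0.21) gained one. Except for tumor 1, the files behind these values are not those of the table columns under the same labels, by the correlations. Those under normal 1 and tumors 2, 3 and 4 are the files with high small intestine and low distal colon levels. The changes in this paragraph can therefore not be read as effects of processing alone.

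With the 4 traced samples alone, limma called 0 genes in each count from table values, from scanner values at the 75th percentile and with the slide, equal to the replicate number, as a block (4808, 4086 and 7352 at an unadjusted p under 0.05). Tcf7l2 was then -1.79, -1.80 and -1.79 with adjusted p of 0.103, 0.181 and 0.105. Of the 3141 called genes tested there, 3141 kept their sign in table values and 3111 in scanner values. This was nearly fixed in advance and is no independent support, because the genes were called on samples that include these 4. Of 3138 called genes with all pair differences, 3137 had the sign of the fit in pair 1 and 3138 in pair 2. With 2 samples per group fewer calls follow from the construction. Lists that lost their call in table values were those of stem cell markers (0.69), cell cycle (0.39) and fibroblast genes (0.27), with enteric neuron (-0.61) and adipocyte genes (-0.93) gaining one. With the slide as a block the same 5 lists changed, with the same values, and Paneth (1.56), endothelial (0.77) and macrophage genes (0.72) also lost their call. In scanner values stem cell (0.69), cell cycle (0.42), Paneth (1.69), endothelial (0.97) and immediate early genes (0.999) lost it, and enteric neuron (-0.22), glycolysis (-0.063) and adipocyte genes (-0.77) gained it. There the fibroblast list turned direction relative to all genes (mean 0.36), where the median of all genes was 0.35.

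Among table settings, the replicate block gave 1869 genes changed and 780 higher, with 1614 genes shared with the 3147, and 38 of 129 named genes lost their call. Under the block the lists of enteric neuron (-0.37) and adipocyte genes (-0.57) passed the threshold, and the block changed no other call of a list, of Tcf7l2 or of Apc. Counts of called members fell by over 1.5 times in several lists, from 20 to 6 for Wnt targets. The block without pair 3 gave 8269 changed, 5341 higher, 2928 lower and 6094 at least 2-fold; stem cell (0.70), cell cycle (0.37) and fibroblast lists (0.55) lost their call, and enteric neuron (-0.49) and adipocyte lists (-0.88) gained one. Array weights gave 15181 changed, 9014 higher, 6167 lower, 8566 at least 2-fold and 13 lists, and moved Apc to -0.50 (adjusted p = 0.0121, the lowest over its 24 alternatives). The weights took the call from the lists of stem cell (0.63), cell cycle (0.24), goblet cell (-0.46), Paneth (1.87), fibroblast (0.27), endothelial (0.63), macrophage (0.80) and immediate early genes (0.85) and gave one to adipocyte genes (-1.34). The share of higher calls was 59.4% with array weights against 48.1% without. Camera with an estimated correlation called 0 lists, with a lowest adjusted p of 0.353, against 28 lists in either direction by fry. The 20 lists that lost their call there keep their means, 2.38 for Wnt target, 0.63 for stem cell, 0.39 for cell cycle, 0.64 for ribosome biogenesis, -1.61 for colonocyte, -0.37 for goblet cell, -0.68 for enteroendocrine, 1.63 for Paneth, -0.42 for pan-epithelial, 0.86 for fibroblast and 2.69 for matrix metalloproteinase genes. They are -0.47 for smooth muscle, 0.85 for endothelial, 0.75 for T and NK cell, 1.03 for macrophage, 3.84 for neutrophil, -0.79 for fatty acid oxidation, 0.84 for immediate early, -1.98 for skeletal muscle and -0.73 for distal colon genes. Directional fry called no shift for cell cycle (0.39), goblet cell (-0.37), fibroblast (0.86), smooth muscle (-0.47) and skeletal muscle genes (-1.98) and a shift for Wnt ligands (1.01), tuft cell (0.49), BMP and TGF-beta (0.55) and sex-linked genes (-0.12). Without a filter smooth muscle (-0.47) and skeletal muscle (-2.02) lost their call and BMP and TGF-beta genes (0.55) gained one. With the limit met on all 8 arrays smooth muscle (-0.43) and skeletal muscle (-1.44) lost it and tuft cell markers (0.62) gained it, and with the mean over probes adipocyte genes (-0.60) gained it. The cause of the changes with block and array weights was not tested. Gpi1 turned to 0.33 with the mean over its probes.

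Leaving out 1 sample gave 21 to 11138 genes changed, 16 to 6860 higher, 5 to 4278 lower and 21 to 7053 at least 2-fold. The counts of genes changed were 855, 379, 21 and 1863 without tumors 1 to 4, and 556, 620, 11138 and 160 without normals 1 to 4. In each of these 8 fits the 3147 genes kept their sign, which shows little, as the genes were called on a fit that shares all but 1 array. Tcf7l2 ranged from -1.88 to -1.60, with adjusted p from 0.00288 to 0.0549, Apc from -0.44 to -0.25 and lists shifted from 18 to 22. The lists whose call changed ranged from -0.64 to -0.20 (goblet cell), 0.43 to 0.53 (tuft cell), 0.50 to 1.19 (fibroblast), -0.81 to -0.23 (smooth muscle), -0.57 to -0.27 (enteric neuron), 0.44 to 0.68 (BMP and TGF-beta), -0.12 to -0.052 (glycolysis), -0.92 to -0.17 (adipocyte), -3.16 to -0.96 (skeletal muscle) and -0.77 to 0.011 (small intestine). Counts without a filter (2368), with the limit met on all 8 arrays (3790), with the mean over probes (2727), with a trended prior (3999) and with the scanner flag (3068) stayed within 1.5 times the 3147. For named genes over all settings on table or traced values, 1463 comparisons kept their direction and stayed called or stayed uncalled. Another 953 kept direction and lost the call, 25 kept direction and gained one, and 1 changed direction. Among the 4 traced columns, that of normal 1 had the smallest share of probes well above background, 55.6%.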

Other observations

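Gene families, grouped by the letters that open their symbols, were tested after the values were seen. Of 223 families with at least 10 genes tested, 6 held more risen genes and 4 more fallen genes than the other genes tested (1-sided Fisher's exact test, BH over 446 tests, genes not being independent). Of these 10 families, all but the carboxylesterases share members with the lists. Of 343 solute carriers, 61 fell and 25 rose (adjusted p = 1.18e-07 for falls; 7 of the 61 are on lists), with the chloride exchanger Slc26a3 at -2.51 ± 0.46, the bicarbonate cotransporter Slc4a4 at -2.51 ± 0.61 and the short-chain fatty acid carrier Slc5a8 at -2.20 ± 0.40, while the cystine transporter Slc7a11 rose by 3.13 ± 0.62. Of 70 cytochrome P450 genes, 18 fell, 1 of them on a list, and 0 rose (adjusted p = 0.000266). Carboxylesterases fell in 9 of 16 genes with 0 up (adjusted p = 8.08e-05), led by Ces1d at -2.32 ± 0.22, and hydroxysteroid dehydrogenases in 7 of 19 with 2 up (adjusted p = 0.0158). Without normal 3 the counts were 87 down and 105 up for solute carriers and 22 down and 24 up for cytochrome P450 genes, where 4278 of all genes fell and 6860 rose. With the pairs as a block they were 42 down and 13 up, and 12 down and 0 up.

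On the rising side, 7 of 11 Cxcl chemokines rose, 5 of them on lists, and 0 fell (adjusted p = 0.000233), among them Cxcl14 at 2.68 ± 0.23, Cxcl3 (under a predicted-gene name in the files, and above the detection limit in 2 of 4 normals) at 5.76 ± 1.18 and Cxcl5 at 4.89 ± 1.16. Of 69 genes whose symbols open with Il, interleukins and their receptors, 13 rose, 5 of them on lists, and 5 fell (adjusted p = 0.0397), with Il1b at 4.64 ± 0.76, Il33 at 2.17 ± 0.24 and Il23a at 3.25 ± 0.58 (above the limit in 2 of 4 normals) up and Il15 at -1.53 ± 0.24 and Il18 at -0.96 ± 0.15 down. Of 53 translation initiation genes of the Eif family, 13 rose and 3 fell (adjusted p = 0.0041). With the pairs as a block, 2 Eif genes rose and 1 fell, and 1 Mcm gene rose. The other families with more rises were Mmp (10 of 19 up, 9 of the 10 on lists, adjusted p = 3.15e-05), Mcm (5 of 10 up, all 5 on lists, adjusted p = 0.0158) and genes whose symbols open with Cd (16 of 87 up, 4 of the 16 on lists, adjusted p = 0.0158). Without normal 3 the rises were 34 for Il, 21 for Eif, 17 for Mmp and 36 for Cd. Of 621 genes whose symbols open with Olfr, 0 rose in the fit of all samples and 461 without normal 3. Rises counted without normal 3 thus include a broad upward shift of that group.

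The counts of called genes were set against all 35 splits of the 8 samples into groups of 4. For genes changed, 1 of 35 splits, the real one, gave as many as 3147, and the highest other gave 2. That share is under 0.05 only if all splits count alike, which the pairing does not allow. The value table was also chosen after some marker levels had been seen, so this share does not exclude chance. The same held for genes higher in tumors (1 of 35, 1515 against 2), genes lower in tumors (1 of 35, 1632 against 2) and genes changed at least 2-fold (1 of 35, 1741 against 2). Because the numbers were taken to pair the samples, the 8 splits that part all 4 pairs are the closer comparison; 8 are too few for a share under 0.05. Among them the others gave 0 genes at most, and with the pairs as a block the real one gave 1869 and the highest other 0. For gene lists shifted by camera, 8 of 35 splits gave as many as 20 and the highest other gave 25, so chance cannot be excluded as the origin of that count. By the mean level of each list, the real split was first of 35 in 18 of 35 lists, the Wnt target, neutrophil, macrophage and colonocyte lists among them, with a lowest adjusted exact p of 0.0556.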
